A study of Mus musculus with 10 samples.

How the data were processed

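RNA from the colorectum of BALB/c mice was sequenced in 10 libraries, 2 in each of 5 groups, after stranded mRNA library preparation, per the labels' protocols. The groups were untreated normal mice (day 0), mice given 2% dextran sodium sulfate (DSS) and a negative control miRNA (NC-miR) with tissue taken on day 2 or day 4, and mice given DSS and miR-29a or miR-29b with tissue taken on day 4. The miRNAs were carried by super carbonate apatite (sCA) and injected into the tail vein on days 1 to 3, per the labels. TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cuffnorm 2.2.1 with the mouse build mm10 are named by the submitters' processing notes, which state no settings.

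The deposited column is headed FPKM per the file headers, but the deposited values are log2 ratios to a baseline of each gene, not FPKM. They run from negative to positive with library medians near 0. The most frequent value of each library was a constant (-0.0427 to 0.0331), read as the floor to which low FPKM values had been raised. With that constant subtracted, a feature was at the floor in the libraries that shared its lowest value, if 2 or more did. These numbered 10344 to 10604 of 23284 features per library. A feature lowest in a single library counted as above the floor in all. The distance of a value above its feature's floor, taken as a power of 2, fell on a grid of 6 significant digits for 99.4% of 6024 values in 9 libraries (within 0.1 of a step). The share was 19.7% with base e and 21.8% with base 10, so base 2 was used. The height of the floor in FPKM is not stated, and the expression level of genes that never reached it cannot be recovered, so differences between libraries are given on the log2 scale without levels. This differs from the log2(FPKM + 1) assumed in the design written before the data were examined. A difference from a group whose libraries all lay at the floor is a lower bound and is written "at least". Such a group has almost no spread between its libraries, so the standard errors and p-values of these features may be too small.

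Features above the floor in both libraries of at least 1 group were tested (13051 of 23284). limma 3.58.1 in R 4.3.3 fitted the 5 group means to all 10 libraries, leaving 5 residual degrees of freedom, with moderation of the variances (3.26 prior degrees of freedom), no trend on expression and no robust option, since the trend needs the expression levels. All p from limma are 2-sided, adjusted by the Benjamini-Hochberg method over the features tested, with calls under 0.05. The comparisons were NC-miR day 2 and NC-miR day 4 against normal, NC-miR day 4 against NC-miR day 2, miR-29a and miR-29b against NC-miR on day 4, their mean against NC-miR on day 4, and miR-29a against miR-29b. Errors printed with a log2 difference are limma standard errors with n = 2 libraries per group. The median standard error over the features was 0.18 (0.16 for the mean of both miR-29 groups). In 5 simulations, values of the 13051 features were drawn from a normal distribution with the moderated variances of limma, and known changes were added. Of 500 genes changed by a log2 of 1 over the 5 simulations, 67% to 79% were called, depending on the comparison. Of those changed by a log2 of 2, 95.6% to 98% were called, with 7.2 to 10.2 false calls per simulation. Genes varied independently in these simulations. The many changed genes also ease the adjustment of p, so the shares may be too high for a comparison with few changes.

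Lists of genes (33, with 694 of 702 listed genes found) were written before the data were examined. Those with at least 5 tested members (31) were tested with camera of limma, with its preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists within a comparison. An estimated correlation and fry were the alternatives. A list's count of changed members is given over all features tested and adjusted over the list alone. In simulations with lists of random genes that varied independently, camera called 25 of 25 shifted lists and 1 of 130 unshifted lists. These simulations cannot give the rate of false calls for lists whose genes vary together. None of the calls of camera held with an estimated correlation, in any comparison, so each called list named in the text is printed with that p. With an estimated correlation the test rests on few residual degrees of freedom, and its power was not simulated. A list that did not pass with it is therefore not shown to be unchanged. Genes named in the text were fixed by rule as well. They were, per comparison, the 10 largest rises and the 10 largest falls among calls with separated groups, omitting provisional symbols, or, where fewer passed, those that passed and the 5 of smallest p in that direction. The rule added up to 4 members of smallest p from each list described, and 14 genes named whatever their values. Any other gene named was chosen after its values were seen, and 1 gene is not reported here. A limit of 2 times the floor in at least 1 group replaced the planned limit on FPKM.

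Features were matched by symbol and older symbol to GENCODE M21, which uses the same assembly as mm10 (22843 of 23284, 98.11%), and coordinates are from it. Sites for the miR-29 seed (TGGTGCT, and TGGTGCTA for the 8-base site) were sought in the longest annotated 3' UTR of each gene, and 3' UTRs under 30 bases counted as not searched. Tested genes with a site were compared with tested genes without, by camera, with 79 control 7-mers of the same base composition (and, added after the values were seen, with 79 control 8-mers made by adding A to each), and with genes without a site matched on 3' UTR length and GC content. For the 8-base site, the matched genes lacked that site but could hold the 7-base site. The adjustment of the seed site p-values over the 14 tests (7 comparisons, 2 site classes) was added after the unadjusted values were seen. The planned matching on expression could not be made. Library scores were compared by an exact permutation test. Correlations between comparisons were taken across genes, which are not independent replicates, and set beside 50 simulations of unchanged groups with the same shared libraries, repeated with each library left out. The simulated genes varied independently, so the simulated SD may be too small for genes that vary together. Transcript length and GC content had a value for 99.1% of tested features.

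Alternatives covered the filter, the scaling of libraries, the libraries in the fit, a replicate block, robust moderation, leaving out each library in turn, and, chosen after seeing the data, a fit without the library shift, without small RNA features, restricted to features above the floor in all 10 libraries, and with GC content and length removed. The share of variance tied to GC content and length, with each library left out, was also chosen then. The files give no read totals, so sequencing depth per library is unknown and no counting error could be computed. The labels do not say which mice each library came from, so the p-values measure the spread between these samples. Replicate numbers were not taken as pairs. The source names of the 4 NC-miR libraries hold a letter and a number and do not say which is the day, so the day was taken from the sample labels. Figures and tables used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.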

Results

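Gene expression was measured by mRNA sequencing of the mouse colorectum in 10 libraries, 2 per group. The miRNAs were carried by sCA, a carbonate apatite carrier for nucleic acids, in mice given DSS, a sulfated polysaccharide used to provoke colitis. The 5 groups were normal mice, DSS mice injected with NC-miR and examined on day 2 or day 4, and DSS mice injected with miR-29a or miR-29b and examined on day 4. The labels of the NC-miR day 2 group also give injections on days 1 to 3. The source names of the 4 NC-miR libraries leave open which part of the name is the day, so all NC-miR values by day rest on the sample labels. The files give no read counts, so depth is unknown, and 12680 to 12940 of 23284 features lay above the floor per library. The deposited log2 values were compared without further normalization.

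How did the colorectum of DSS mice given NC-miR differ from normal on day 2? Genes induced by type I interferon were far above normal, and genes of the circadian clock moved in opposite directions. Normal mice had neither DSS nor injections, so comparisons with them cannot separate DSS, the injections and the day of collection. Of 30 measured type I interferon genes, 26 rose and 0 fell (30 rose adjusted over the list alone), with a median log2 difference of 3.42. Ifit1 (mm10 chromosome 19, 34640871 to 34650009), which encodes an antiviral RNA-binding protein, rose 56.7-fold (log2 5.82 ± 0.62, n = 2 per group, limma adjusted p = 0.00595). The antiviral gene Oasl2 (chromosome 5, 114896936 to 114912234) rose by 5.12 ± 0.39 on the log2 scale, the ubiquitin-like modifier Isg15 by 5.10 ± 0.45, and Ddx60 by 4.44 ± 0.27. Usp18, which removes Isg15 from proteins, rose by 4.59 ± 0.62. Ifi44 and Oas3 lay at the floor in both normal libraries and rose at least 37.6-fold and at least 22.9-fold. Ifit3 rose by 5.60 ± 0.79, a value left uncertain by a near-identical neighbouring gene. The list's camera adjusted p was 3.42e-51, with adjusted p = 0.221 with an estimated correlation, and 0.0104 by fry. Among 35 interferon-gamma response and antigen presentation genes, 12 rose and 0 fell (26 rose adjusted over the list alone), including the GTPases Gbp3 (3.34 ± 0.37) and Igtp (3.12 ± 0.37), and the peptide transporter Tap1 (1.71 ± 0.20). Their median was 1.48 (adjusted p = 0.221 with an estimated correlation, 0.0262 by fry).

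On the same day, 8 of 16 clock genes rose and 4 fell (9 and 4 adjusted over the list alone). The output regulator Dbp (chromosome 7, 45705088 to 45710203) rose 21.7-fold (log2 4.44 ± 0.19, limma adjusted p = 9.71e-05), Tef rose by 2.40 ± 0.13 and Nr1d2, a repressor of Arntl, by 2.89 ± 0.20. Gm129 (also called Ciart), at the floor in both normal libraries, rose by at least 3.70 on the log2 scale. Arntl, which encodes the core activator BMAL1, fell by 2.14 ± 0.20, its partner Npas2 by 1.73 ± 0.18, Nfil3 by 2.2 ± 0.31 and the repressor Cry1 by 1.66 ± 0.25. The clock list's median was 1.04 (adjusted p = 0.221 with an estimated correlation, 0.00118 by fry). Of 22 cholesterol synthesis genes, Idi1 alone rose (1.04 ± 0.14), 7 rose adjusted over the list alone, and the median was 0.45 (adjusted p = 0.221 with an estimated correlation). All 15 B and plasma cell genes were lower in these libraries, with a median of -1.46 (adjusted p = 0.409 with an estimated correlation). None of them passed over all genes tested and 15 fell adjusted over the list alone, with the chemokine receptor gene Cxcr5 at -1.41 ± 0.29 (limma adjusted p = 0.0666) and Fcer2a at -2.28 ± 0.58 (0.128). Adipocyte genes had a median of 0.94 and goblet cell genes of 0.28 (adjusted p = 0.49 and 0.459 with an estimated correlation), with 0 members of either passing. These medians were 0.55 without normal replicate 1 and 0.18 without NC-miR day 2 replicate 2. The normal libraries themselves differed on adipocyte genes (-0.47 and 0.47 from their mean). Of 11 inflammatory cytokine and chemokine genes, Ccl8, which encodes a monocyte attractant, rose (1.94 ± 0.31, and alone adjusted over the list), with a list median of 0.27 (adjusted p = 0.459 with an estimated correlation). This call of camera was lost without NC-miR day 2 replicate 1 (0.112) or normal replicate 2 (0.104). Of 32 absorptive colonocyte genes, Trpm6 alone passed (it fell), and 7 rose and 4 fell adjusted over the list alone. The median was 0.20 (adjusted p = 0.409 with an estimated correlation), and between 0.13 and 0.29 with a library left out. This call was lost without NC-miR day 2 replicate 2 (0.0723) or normal replicate 2 (0.0847). Monocyte and macrophage genes had a median of 0.19, with 0 of 17 passing (adjusted p = 0.755 with an estimated correlation), with 0.04 without normal replicate 1 (0.305), 0.12 without NC-miR day 2 replicate 1 (0.0689) and 0.43 without normal replicate 2. The precursor feature Mir29c (chromosome 1, 195037547 to 195037634) lay at the floor in both day 2 libraries and above it in the 8 others, at least 471-fold lower than normal. It lies within a noncoding host gene and opposite Cd46 in the annotation, so its assigned reads are uncertain. Other falls were of Cpm (-1.82 ± 0.17), the arginase gene Arg2 (-1.58 ± 0.29), Atg16l2 (-1.39 ± 0.18), the magnesium channel gene Trpm6 (-1.29 ± 0.20) and Adc (-1.10 ± 0.16).

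In all, limma called 159 of 13051 features in this comparison, 139 higher and 20 lower, and 1988 had an unadjusted p under 0.05. The called genes named above and kept in each of the 10 fits that left out 1 library were Oasl2, Isg15, Ddx60, Dbp, Tef, Gm129, Nr1d2 and Mir29c. The other called genes named lost their calls without normal replicate 2, with a highest adjusted p between 0.0532 (Cpm) and 0.292 (Arg2). The count was 34 or 16 without normal replicate 1 or 2, 68 or 273 without NC-miR day 2 replicate 1 or 2, 97 without either miR-29a library, 99 without either miR-29b library, and 26 in a fit to the 4 libraries compared. NC-miR day 2 replicate 1 had the higher mean score of the type I interferon genes (4.18 above normal, against 2.76 in replicate 2).

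**Figure D1:**
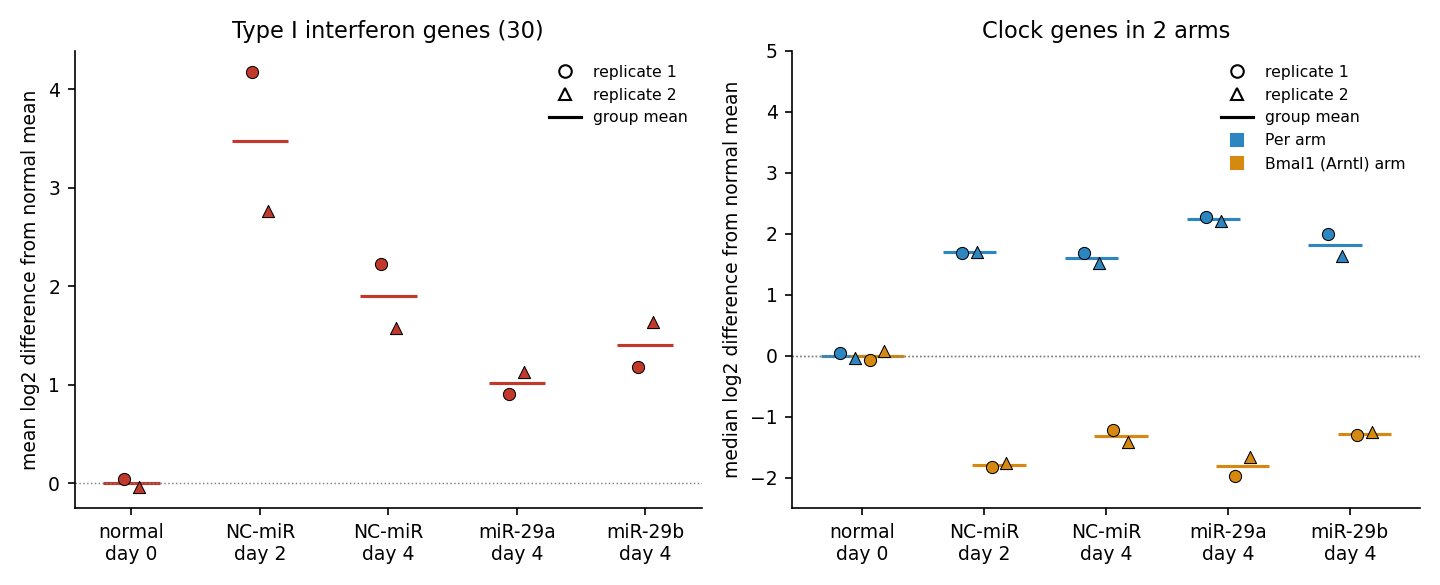
Left, mean log2 difference from the normal mean of 30 type I interferon genes in each library (points) and group (lines). Right, median log2 difference of 11 clock genes of the Per arm and 5 of the Bmal1 arm, by library. NC-miR day 2 libraries lie highest for interferon genes (4.18 and 2.76), and the 8 DSS libraries have the arms on opposite sides of normal.

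By day 4 with NC-miR, the lists of interferon, clock, sterol and absorptive cell genes again passed camera against normal, but not with an estimated correlation. Dbp rose by 4.21 ± 0.19 (limma adjusted p = 0.000148), Tef by 2.25 ± 0.13, Nr1d1, which encodes the repressor REV-ERB alpha, by 3.67 ± 0.48, Nr1d2 by 2.76 ± 0.20, and Gm129 by at least 3.51. Arntl fell by 2.2 ± 0.20, Nfil3 by 2.12 ± 0.31 and Npas2 by 1.32 ± 0.18. Of the 16 clock genes, 7 rose and 3 fell (9 and 4 adjusted over the list alone), and the list's median was 0.85 (adjusted p = 0.123 with an estimated correlation, 0.00085 by fry). Of 30 type I interferon genes, 8 rose (24 adjusted over the list alone), among them Oasl2 (3.70 ± 0.39), Oas3 (at least 3.65), Isg15 (3.09 ± 0.45), Rtp4 (2.62 ± 0.37), Ifi27l2a (2.52 ± 0.33) and Herc6 (1.89 ± 0.27). Their median was 1.66 (adjusted p = 0.313 with an estimated correlation, 0.0663 by fry), and Ddx60, outside the list, rose by 3.38 ± 0.27. Among interferon-gamma genes, 0 of 35 passed limma (6 rose adjusted over the list alone), with a median of 0.39 (adjusted p = 0.816 with an estimated correlation). That median was 0.55 in NC-miR day 4 replicate 1 and 0.18 in replicate 2. Of 22 cholesterol synthesis genes, Idi1 (1.44 ± 0.14) and Sc4mol (1.09 ± 0.17) rose, 17 rose adjusted over the list alone, and the median was 0.67 (adjusted p = 0.123 with an estimated correlation, 0.0105 by fry). Of 32 absorptive colonocyte genes, the water channel gene Aqp4 rose (1.82 ± 0.22), 14 rose and 3 fell adjusted over the list alone, and the median was 0.39 (adjusted p = 0.123 with an estimated correlation, 0.0105 by fry). Goblet cell genes had a median of 0.37 and unfolded protein response genes of 0.18, with 0 members passing in either (adjusted p = 0.313 and 0.379 with an estimated correlation). B and plasma cell genes had a median of -1.53, with 0 of 15 passing and 10 lower adjusted over the list alone (adjusted p = 0.32 with an estimated correlation). Mast cell and eosinophil genes had a median of -0.56 (-0.97 to -0.49 with a library left out), with 0 of 5 passing and 2 lower adjusted over the list alone. Their adjusted p was 0.32 with an estimated correlation, and the call of camera was lost without normal replicate 2 or either miR-29b library.

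Other genes changed on day 4 were Pla2g2a (2.67 ± 0.39), which encodes a secreted phospholipase, and, among the falls, the neuroglobin gene Ngb (-2.0 ± 0.25), Cpm (-1.75 ± 0.17), Ypel2 (-1.53 ± 0.20), Bok (-1.51 ± 0.23) and the ribosomal protein gene Rpl30 (-1.64 ± 0.23), whose reads pseudogene copies could share. Snord16a (chromosome 9, 64175423 to 64175521), a small nucleolar RNA inside Rpl4, lay at the floor in both NC-miR day 4 libraries and above it in the 8 others, at least 498-fold lower than normal. Rpl4, named after its values were seen, differed by -0.12 ± 0.17 (limma adjusted p = 0.765). Markers of tissues other than glandular epithelium differed between the NC-miR day 4 libraries. Squamous epithelium genes were high in replicate 1 alone (median 3.33 against -0.15 in replicate 2, with 8 of 9 members highest in replicate 1), and smooth muscle genes were low in replicate 2 (-0.45 against -0.01). These lists had group medians of 1.42 and -0.23 (adjusted p = 0.816 and 0.83 with an estimated correlation), and the first had adjusted p = 0.81 without NC-miR day 4 replicate 1, the second 0.793 without replicate 2.

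On day 4 limma called 50 features, 35 higher and 15 lower, with 1985 at an unadjusted p under 0.05. Of the called genes named for day 4, Dbp, Tef, Gm129, Nr1d2 and Ddx60 kept their calls in each fit that left out 1 library. The others lost theirs without normal replicate 2, with a highest adjusted p between 0.102 (Cpm) and 0.249 (Bok), and the interferon-gamma list lost its call without NC-miR day 4 replicate 1 (camera adjusted p = 0.113). The count was 10 without normal replicate 1 or NC-miR day 4 replicate 1, 6 without normal replicate 2, 33 without NC-miR day 4 replicate 2, 25 without either miR-29a library, 82 without either NC-miR day 2 library, 31 without the filter and 20 in a fit to the 4 libraries compared. The day 2 and day 4 differences from normal correlated across 13051 genes (r = 0.69, rho = 0.70). They share the normal libraries, for which simulated unchanged groups gave r = 0.51 (covariance 0.157 against 0.035 simulated), and part of the value may come from these shared libraries. The comparisons had 36 calls of like direction in common, part of which may also come from the shared libraries.

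**Figure D2:**
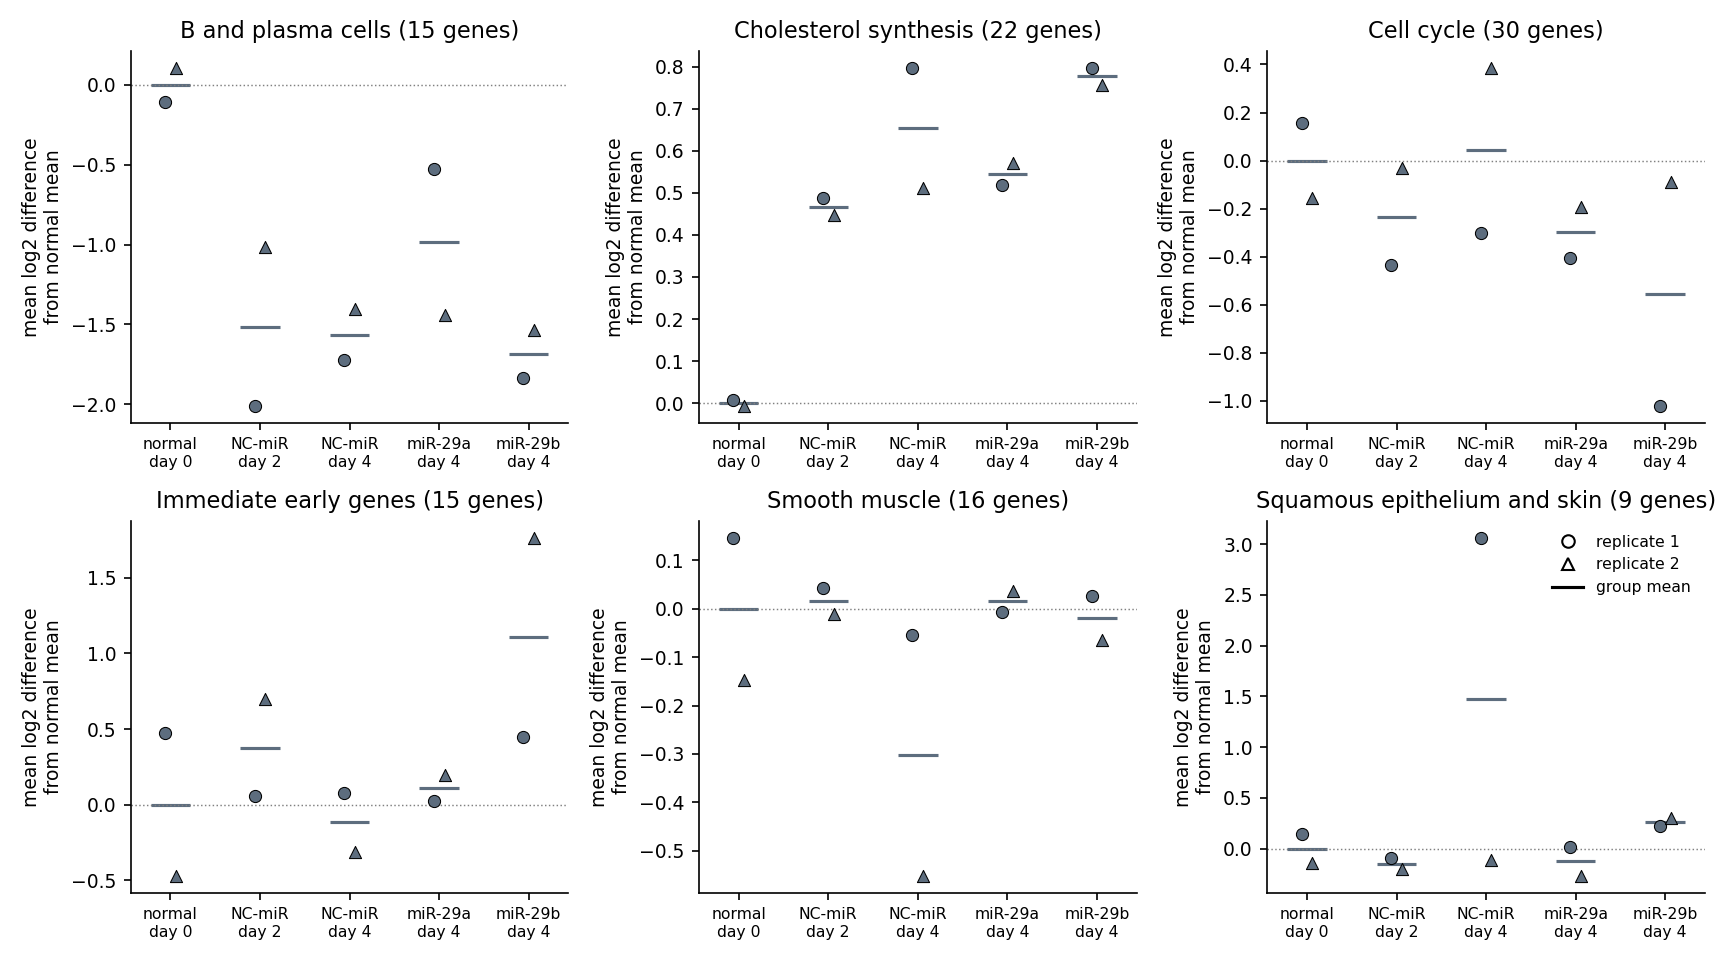
Mean log2 difference from the normal mean of 6 gene lists in each library (points) and group (lines). B and plasma cell genes lie below normal in the 8 DSS libraries, and NC-miR day 4 replicate 1 stands apart for squamous genes (3.06) as replicate 2 does for smooth muscle genes (-0.55).

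How did NC-miR colorectum change between day 2 and day 4? All 30 type I interferon genes were lower on day 4 (median -1.32), although 0 passed over all genes tested and 27 were lower adjusted over the list alone. Those of smallest p were Bst2 (-1.85 ± 0.25, limma adjusted p = 0.277), Xaf1 (-1.48 ± 0.31, 0.483) and Isg15 (-2.01 ± 0.45, 0.483). Outside the list, the smallest p belonged to Abcg1 (-1.21), Pilra (-0.88), H2-T24 (-1.94), Ceacam2 (1.06), Pop1 (0.79), Spink5 (1.21) and Pspn (0.85), with limma adjusted p of 0.289 to 0.483. Interferon-gamma genes had a median of -0.96, with 23 of 35 lower adjusted over the list alone and Tap1 at -1.32 ± 0.20 (limma adjusted p = 0.343). Both lists passed camera (adjusted p = 8.39e-32 and 2.83e-26), with adjusted p = 0.384 with an estimated correlation for each. Without NC-miR day 2 replicate 1 their medians were -0.82 and -0.61. limma called 2 features, both small RNA precursors at the floor in 1 of the groups, and 837 had an unadjusted p under 0.05. The calls were Mir29c (at least 367-fold higher on day 4, adjusted p = 0.00834) and Snord16a (at least 892-fold lower, adjusted p = 0.0357). A group at the floor has almost no spread, so these p-values may be too small. Without NC-miR day 2 replicate 2 the count was 94 (92 lower), without NC-miR day 4 replicate 2 it was 6, and without any other library it was 0 or 1.

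What did miR-29a add on day 4? No single gene passed limma against NC-miR (0 of 13051, with 996 at an unadjusted p under 0.05), and the difference with the smallest p was again Snord16a (at least 587-fold higher, adjusted p = 0.116). Next came Ugt1a1, a bilirubin-conjugating enzyme gene (1.22 ± 0.14, limma adjusted p = 0.137), and, with adjusted p of 0.328, Rpl30 (1.60 ± 0.23), the ubiquitin-like gene Ubd (0.93 ± 0.14), Wdr54 (1.13 ± 0.18), Pspn (-1.02 ± 0.18), Aqp4 (-1.32 ± 0.22), Mgat4c (-0.82 ± 0.14) and Homer1 (-0.81 ± 0.14). Type I interferon genes were lower than with NC-miR in 30 of 30 cases (median -0.80), with 0 lower by limma even when adjusted over the list alone, as for Oas2 (-2.06 ± 0.59), Oasl2 (-1.26 ± 0.39) and Herc6 (-0.95 ± 0.27). The camera adjusted p was 1.42e-14, with adjusted p = 0.808 with an estimated correlation, and the median was -0.48 without NC-miR day 4 replicate 1. Unfolded protein response genes were also lower (median -0.26, adjusted p = 0.509 with an estimated correlation), with the chaperone gene Hspa5 at -0.50 ± 0.15, and clock genes were higher (median 0.28, 6 of 16 adjusted over the list alone, adjusted p = 0.509 with an estimated correlation), with Per3 at 0.77 ± 0.15. Matrix genes known as miR-29 targets had a median of 0.19, with 23 of 25 higher (adjusted p = 0.859 with an estimated correlation), and 0.11 with GC content and length removed. This direction depended on 1 library, since the median was -0.01 without NC-miR day 4 replicate 2 and 0.41 without replicate 1, and the call was also lost without miR-29a replicate 2 (0.0749). Against normal, the medians of these genes were 0.15 and -0.33 in the NC-miR day 4 libraries and 0.10 and 0.09 in the miR-29a libraries. Fibroblast (0.30), smooth muscle (0.34) and T and NK cell genes (0.49, 3 of 9 adjusted over the list alone) were higher and cell cycle genes lower (-0.44), with adjusted p of 0.808 to 0.859 with an estimated correlation. Smooth muscle genes were low in NC-miR day 4 replicate 2 itself, and without that library these calls were lost, with camera adjusted p = 0.256 for matrix, 0.464 for fibroblast, 0.6 for smooth muscle, 0.185 for T and NK cell and 0.871 for cell cycle genes. The medians were then 0.07 for fibroblast, 0.07 for smooth muscle and -0.18 for cell cycle genes, and that of cell cycle genes was -0.21 without miR-29a replicate 1. Squamous genes (median -1.34, adjusted p = 0.808 with an estimated correlation) lost their call without NC-miR day 4 replicate 1 (0.542), and without miR-29a replicate 1 the calls of T and NK cell (0.139), fibroblast (0.0684) and clock genes (0.111) were lost. B and plasma cell genes (0.50) and dendritic cell genes (0.25) were higher with 0 members passing (adjusted p = 0.859 and 0.808 with an estimated correlation), and without miR-29a replicate 1 these medians were 0.11 (0.74) and 0.13 (0.426). Both calls were also lost without NC-miR day 4 replicate 1 (0.107 and 0.0686). The dendritic one was lost too without NC-miR day 4 replicate 2 (0.256), without either miR-29b library (0.0603) and with GC content and length removed (0.0605). The count of genes was 3 without NC-miR day 4 replicate 2 and 1 without miR-29a replicate 2 or either NC-miR day 2 library.

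miR-29b against NC-miR on day 4 likewise gave 0 genes past limma, with 1627 at an unadjusted p under 0.05. The smallest adjusted p, 0.093, was shared by Snord16a (at least 543-fold higher), Id1, an inhibitor of helix-loop-helix factors (1.75 ± 0.20), and Serpina9 (-1.40 ± 0.16), followed by the lectin gene Lgals3 (1.08 ± 0.13, 0.116), Fbxl15 (1.07 ± 0.14, 0.116), Zfp688 (0.96 ± 0.13, 0.14), Lipo1 (-0.82 ± 0.12, 0.194), Cep128 (-0.91 ± 0.14, 0.198) and Ska3 (-1.34 ± 0.23, 0.259). Immediate early genes, which respond within minutes to stimulation or handling, were higher in 15 of 15 cases (median 1.02, 4 adjusted over the list alone), as for Junb (1.41 ± 0.38), Ier2 (1.18 ± 0.30) and Jun (1.02 ± 0.25). Their medians against the normal mean were 1.47 in miR-29b replicate 2 and 0.26 in replicate 1. They were 0.26 and -0.27 in the NC-miR day 4 libraries, and 0.50 and -0.50 in the normal libraries themselves. The median difference from NC-miR was 0.62 without miR-29b replicate 2. Cell cycle genes were lower (median -0.69), with Bub1 at -1.54 ± 0.38 and Top2a at -1.50 ± 0.43, but the median was -0.11 without miR-29b replicate 1 (camera adjusted p = 0.466) and -1.23 without replicate 2. Against normal, the cell cycle medians were -1.04 and -0.01 in the miR-29b libraries and -0.24 and 0.39 in the NC-miR day 4 libraries. Type I interferon genes were lower in 27 of 30 cases (median -0.45), with Oasl2 at -1.16 ± 0.39. Endothelial (0.32, with Vwf at 0.74 ± 0.16), smooth muscle (0.37, and 0.18 with GC content and length removed) and T and NK cell genes (0.48, with Cd3d at 0.93 ± 0.19) were higher, and 0 members of the 6 lists passed over all genes tested. Each of the 6 lists had adjusted p = 0.893 with an estimated correlation. Without NC-miR day 4 replicate 1 the interferon median was -0.21 (camera adjusted p = 0.13). Without NC-miR day 4 replicate 2 the calls of cell cycle (0.456), endothelial (0.486), smooth muscle (0.764) and T and NK cell genes (0.204) were lost, and without miR-29b replicate 1 only immediate early genes of the 6 kept their call. Across 12422 genes, GC content and transcript length accounted for 32.4% of the variance of this comparison, against 9.56% for miR-29a. Without miR-29b replicate 2 the share was 15.1%, and without NC-miR day 4 replicate 2 it was 20.8%. Relative to the mean of all libraries, GC content correlated with expression at r = 0.24 and 0.44 in the miR-29b libraries and -0.14 and -0.37 in the NC-miR day 4 libraries, and log2 transcript length at 0.08 and -0.43 and at 0.23 and 0.19. The count of genes was 4 without NC-miR day 4 replicate 2 and 1 without miR-29b replicate 2 or either NC-miR day 2 library.

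Of the 14 miR-29 target and cytokine genes named whatever their values, those tested did not pass limma in any comparison. With miR-29a and miR-29b the differences from NC-miR were 0.29 ± 0.22 and 0.27 ± 0.22 for Col1a1, 0.06 ± 0.17 and -0.01 ± 0.17 for Col3a1, 0.05 ± 0.17 and 0.03 ± 0.17 for Col4a1, and 0.24 ± 0.22 and -0.03 ± 0.22 for Dnmt3a. Mcl1 differed by -0.04 ± 0.15 and -0.09 ± 0.15, Cdk6 by 0.60 ± 0.34 and 0.14 ± 0.34, Tgfb1 by -0.21 ± 0.28 and -0.06 ± 0.28, and Il1b by 0.36 ± 0.38 and 0.86 ± 0.38. Il6, Il23a, Il12b and Tet1 lay at the floor in all 10 libraries, and Dnmt3b and Tnf rose above it in 1 and 2 libraries, so none of these was tested.

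Were genes with a miR-29 seed site lower after miR-29? Both injected miRNAs share this seed, and 1881 tested genes had the 7-base or 8-base site in the 3' UTR against 10541 without. The median difference between these sets was -0.04 for miR-29a (limma camera, adjusted p = 0.263 over the 14 tests of this family) and -0.08 for miR-29b (adjusted p = 0.0583), and -0.11 for miR-29b over the 384 genes with the 8-base site (adjusted p = 0.0365). With an estimated correlation the miR-29b values were p = 0.183 and 0.133. Genes with a site had longer 3' UTRs (median 2369 against 984 bases), and against genes matched on 3' UTR length and GC content the miR-29b difference was -0.02. For the 8-base site it was -0.01, but the matched genes could hold the 7-base site, which may have made this difference smaller. As low a difference as that of the 7-base or 8-base site came from 18 of 79 control 7-mers. For the 8-base site it came from 2 of 79 control 7-mers and 22 of 79 control 8-mers, each a control 7-mer followed by A. Library values of the site genes, with GC content and length removed, did not separate the 4 miR-29 libraries from NC-miR day 4 (exact permutation test, 2-sided p = 0.533, the smallest possible being 0.0667). With the same removal, the planned lists of miR-29 targets were not lower than with NC-miR. The 32 targets outside the matrix had medians of 0.08 with miR-29a and 0.06 with miR-29b (camera adjusted p = 0.178 and 0.124). The 25 matrix targets had 0.11 and 0.05 (0.0264 and 0.842). The NC-miR day 4 libraries lay apart on the matrix targets (0.15 and -0.33 from normal as deposited).

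**Figure D3:**
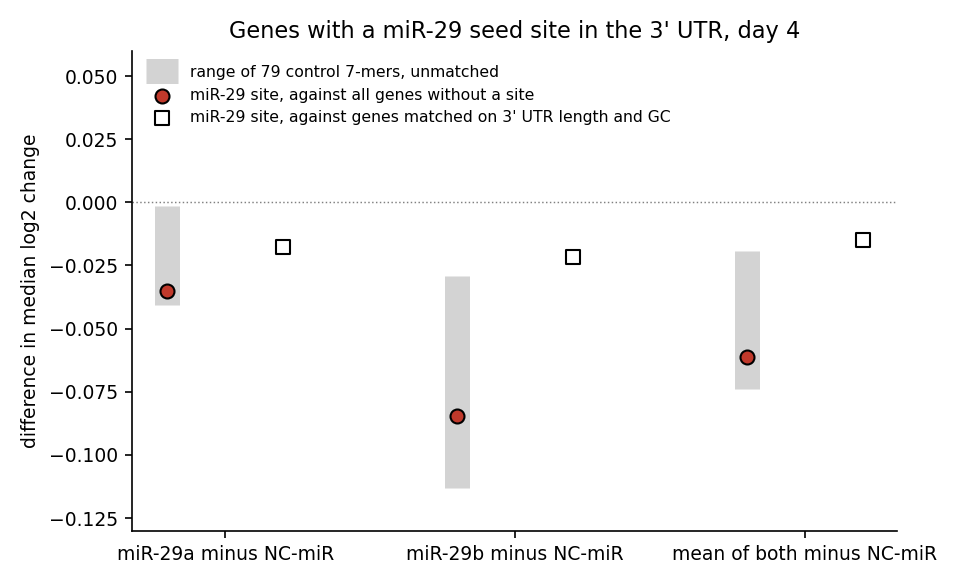
Difference in median log2 change on day 4 between genes with a miR-29 seed site and genes without (filled points), against matched genes (open squares), with the range of 79 control 7-mers (bars). The miR-29b value of -0.08 lies inside its control range, -0.11 to -0.03.

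Did the miR-29 groups differ from each other or share a change? Between miR-29a and miR-29b, limma called 0 genes (970 at an unadjusted p under 0.05). Those of smallest p, each with adjusted p = 0.665, were Serpina9 (1.06), Epyc (1.15), Cep128 (0.81), Iqcb1 (0.75), Gkn3 (0.84), Lgals3 (-0.82), Fam171a2 (-0.66), Mgat4c (-0.76) and the guanylin gene Guca2a (-1.08). Immediate early genes were lower with miR-29a (median -0.97) and B and plasma cell genes higher (0.74), each with adjusted p = 0.783 with an estimated correlation, and these medians were -0.57 without miR-29b replicate 2 and 0.23 without miR-29a replicate 1. miR-29a replicate 1 also stood apart from replicate 2 in the mean scores of 4 red blood cell genes (0.29 against -3.28), too few to test as a list, and of adipocyte genes (1.25 against 0.05). Other pairs differed in these too: red blood cell scores were -3.06 and -0.42 in NC-miR day 4, and adipocyte scores 0.08 and 1.09 in miR-29b. Against NC-miR, the mean of both groups gave 1 call, with 1405 features at an unadjusted p under 0.05. The call was Snord16a (at least 565-fold higher, limma adjusted p = 0.0401). It lay at the floor in both NC-miR day 4 libraries, so this p may be too small. Next came Rpl30 (1.63), Zfp688 (0.85), Id1 (1.29), Ugt1a1 (0.88), Tspan4 (0.96), Apol7a (-0.73), Serpina9 (-0.87), Pspn (-0.95) and Homer1 (-0.74), which did not pass. The Snord16a call was lost without either NC-miR day 4 library, among others, and the count was 5 without NC-miR day 4 replicate 2. The type I interferon median for this mean was -0.60 (adjusted p = 0.661 with an estimated correlation) and -0.31 without NC-miR day 4 replicate 1. Library scores of these genes averaged 1.21 above normal over the 4 miR-29 libraries and 1.90 over the NC-miR day 4 libraries (exact permutation test, 2-sided p = 0.133, the smallest possible being 0.0667). The 2 miR-29 differences from NC-miR correlated across genes with r = 0.56 (rho = 0.57), where simulated unchanged groups sharing the NC-miR libraries gave 0.49 ± 0.036 (SD). The covariance was 0.0717 against 0.0337 simulated, and part of the excess may come from the shared libraries. The simulated genes varied independently, so the SD may be too small. Without NC-miR day 4 replicate 1 the correlation was 0.69 and without replicate 2 it was 0.67, where simulated unchanged groups with a single NC-miR library gave 0.67 in both cases.

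Did genes that differed between NC-miR day 2 and normal lie nearer to normal with miR-29? These groups differ in DSS, the injections and the day of collection together. Of the 139 genes that rose by day 2 with NC-miR, a set that shares no library with the day 4 comparison, 98 (70.5%) lay below NC-miR in the miR-29 mean, with a median of -0.30 (-0.35 for miR-29a and -0.21 for miR-29b). The median over all 13051 features was 0.02. The count gives the side of NC-miR day 4, whether or not that group lay above normal, and not the distance from normal. It was not repeated with a library left out. Of the 139 genes, 38 belonged to the interferon lists and 8 to the clock list, and the share was not taken without these genes. Of the 20 that fell by day 2, 9 (45%) lay below NC-miR. Across all genes tested, the mean miR-29 difference correlated with the day 2 difference from normal at r = -0.16 (rho = -0.18), and at -0.09 without NC-miR day 4 replicate 1. Simulated unchanged groups gave -0.01 ± 0.054 (SD), but with genes that varied independently, so this SD may be too small. Against the day 4 difference from normal, which shares the NC-miR day 4 libraries, r was -0.57, with -0.58 in simulated unchanged groups.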

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

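These results were flagged because the paired groups differed by a test of the difference itself, either NC-miR day 4 against NC-miR day 2 or miR-29a against miR-29b. The comparisons, the lists and the use of limma and camera were planned before the data were examined. The scale, the filter and the omission of the trend departed from that plan. The removal of GC content and length was chosen after the result was seen. Between day 2 and day 4 with NC-miR, the median log2 difference was -1.32 for type I interferon genes (camera adjusted p = 8.39e-32, adjusted p = 0.384 with an estimated correlation) and -0.96 for interferon-gamma and antigen presentation genes (2.83e-26 and 0.384). Smooth muscle genes differed by -0.33 (8.12e-06, and 0.561 with an estimated correlation), squamous epithelium genes by 1.27 (0.000161 and 0.561) and absorptive colonocyte genes by 0.13 (0.00035 and 0.384). The absorptive median was 0.22 with GC content and length removed, and also 0.22 without NC-miR day 4 replicate 2. Cholesterol synthesis genes differed by 0.28 (0.00327 and 0.561), unfolded protein response genes by 0.19 (0.00451 and 0.561), immediate early genes by -0.46 (0.00451 and 0.687), adipocyte genes by -0.50 (0.00686 and 0.762) and cell cycle genes by 0.29 (0.00875 and 0.94). Of these 10 lists, 0 had a member past limma over all genes tested. Leaving out NC-miR day 4 replicate 1 ended the calls of squamous (0.757), unfolded protein response (0.0668) and cholesterol genes (0.552). Leaving out NC-miR day 4 replicate 2 ended those of smooth muscle (0.294), cell cycle (0.333), immediate early (0.16) and adipocyte genes (0.232). Leaving out NC-miR day 2 replicate 1 ended those of cell cycle (0.453) and adipocyte genes (0.111), and leaving out NC-miR day 2 replicate 2 those of unfolded protein response (0.117), cholesterol (0.075) and immediate early genes (0.117).

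Mir29c differed by at least 8.52 (limma adjusted p = 0.00834) and Snord16a by -9.80 or further (0.0357), since each lay at the floor in 1 of these groups. A group at the floor has almost no spread, so these p-values may be too small. Without NC-miR day 2 replicate 1 or either miR-29b library Mir29c lost its call (highest adjusted p = 0.0639), and Snord16a kept its call in 2 of 10 fits that left out 1 library (highest adjusted p = 0.28).

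Between miR-29a and miR-29b, immediate early genes differed by -0.97 (camera adjusted p = 3.95e-06, adjusted p = 0.783 with an estimated correlation), B and plasma cell genes by 0.74 (0.000302 and 0.783), unfolded protein response genes by -0.22 (0.000399 and 0.783) and cholesterol synthesis genes by -0.30 (0.00188 and 0.783). Type I interferon genes differed by -0.37 (0.00294, and 0.916 with an estimated correlation), mitochondrial respiration genes by -0.12 (0.0154 and 0.916), goblet cell genes by -0.19 (0.0476 and 0.783) and crypt stem cell and Wnt target genes by 0.27 (0.0476 and 0.783). Of these 8 lists, 0 had a member past limma. Without miR-29a replicate 1 the calls of type I interferon (0.17), B and plasma cell (0.243), goblet cell (0.5) and crypt stem cell genes (0.4) were lost. Crypt stem cell genes also lost theirs without either normal library (0.0555), and goblet cell genes with GC content and length removed (-0.11, 0.0675), without either NC-miR day 2 or normal library (0.0521) or either NC-miR day 4 library (0.0552). Without miR-29b replicate 1 those of B and plasma cell (0.0766), crypt stem cell (0.586) and cholesterol genes (0.0783) were lost, and without miR-29b replicate 2 those of type I interferon (0.485), goblet cell (0.295) and mitochondrial genes (0.983).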

How the results depend on the processing

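The simulations with a library left out and these 4 alternatives were chosen after the data were seen, namely GC and length correction, no library shift, removal of small RNA features, and features above the floor in all 10 libraries. When a library was left out, 0 of the 60 called results for single named genes and 41 of the 338 others changed sign. Of all these results, 391 kept their side of the threshold after GC and length correction. The number was 397 after rescaling and 386 with a replicate block (7, 1 and 12 did not). A change of direction was counted only for results past the threshold in either fit, so others among those kept may have changed sign. Of 66 called lists, 63, 65 and 64 kept their call under the same settings, 0 with an estimated correlation and 7 by fry. Changed features numbered 26 for NC-miR day 2 against normal (159 as reported) and 20 for NC-miR day 4 against normal (50 as reported) with only the groups compared in the fit, where fewer libraries estimate the spread. The same setting gave 2 for miR-29a and 3 for miR-29b against NC-miR and 2 between them (0 as reported for each). NC-miR day 4 against normal gave 31 without the filter, where more features are tested, and 30 with a replicate block, although the replicate pairing rests on shared numbers alone. NC-miR day 4 against NC-miR day 2 (2 as reported) gave 1 without the filter, 1 with robust moderation, 0 for features above the floor in all libraries and 0 without small RNA features. The mean of the miR-29 groups (1 as reported) gave 0 in each of these 4 settings, 2 of which remove the called features by construction. GC and length correction gave 2 for miR-29a and 1 for miR-29b, the cause of which was not tested.

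When each library was left out in turn, the lone library left in its group being assumed to vary like the others, the counts ran from 16 to 273 for NC-miR day 2 and from 6 to 82 for NC-miR day 4 against normal, and from 0 to 94 between them. They ran from 0 to 3 for miR-29a, from 0 to 4 for miR-29b, from 0 to 1 for miR-29a against miR-29b and from 0 to 5 for the mean. Lists past camera numbered 10 for NC-miR day 2 (8 to 12 on leaving out a library, 4 by fry), 11 for NC-miR day 4 (10 to 16, 3 by fry), 10 between them (9 to 15, 0 by fry), 11 for miR-29a (6 to 14, 0 by fry), 6 for miR-29b (2 to 14, 0 by fry), 8 between the miR-29 groups (6 to 12, 0 by fry) and 10 for the mean (6 to 12, 0 by fry), and 0 in every comparison with an estimated correlation. The difference of seed site genes was -0.0848 for miR-29b and -0.0611 for the mean, with p = 0.183 and 0.236 by an estimated correlation, and -0.0217 (p = 0.622) and -0.015 (p = 0.586) against matched genes. Lists whose camera direction turned were squamous genes without NC-miR day 4 replicate 1, with medians from -0.1524 there to 3.3297 in NC-miR day 4 against normal and from -2.706 to 0.1305 there in the mean of the miR-29 groups, and, without NC-miR day 4 replicate 2, cell cycle genes between the NC-miR days (-0.0846 there, up to 0.5869), matrix targets with miR-29a (-0.0051 there, up to 0.4103) and cell cycle genes with miR-29a (-0.1751 there, down to -0.6754). The correlation across genes ran from 0.4681 to 0.6868 for miR-29a with miR-29b, where unchanged groups simulated for the same settings gave 0.417 and 0.669, so the upper end shows no added likeness, and, with the day 2 difference from normal, from -0.209 to -0.134 for miR-29a, -0.114 to -0.0191 for miR-29b and -0.179 to -0.0857 for the mean. For the mean with the day 4 difference from normal it ran from -0.685 to -0.512, against -0.731 and -0.47 simulated. The pseudocount of 0.1, the filter at an FPKM of 5, the trend on expression and a test on read counts were not run, since the files hold neither levels nor counts, and depth sets no known limit here.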

Other observations

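All 10 explanations below were tested after the result was seen, and the correction for GC content and length was also chosen then.

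Clock genes differed between the 8 DSS libraries and the normal libraries. A bias from GC content and length was argued against by an arm difference of 3.43 for NC-miR day 2 after their removal. The time of day at which tissue was taken, which the labels do not give, and DSS or the injections acting on the clock cannot be told apart, since every normal mouse was untreated and examined on day 0. The Per arm lay above and the Bmal1 arm below the normal mean in 8 of 8 DSS libraries, which restates the pattern, as does the arm difference of 3.43 before correction. This difference was 2.91 with NC-miR on day 4, 4.06 with miR-29a and 3.10 with miR-29b.

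Type I interferon genes lay lower in the miR-29 libraries than in NC-miR day 4. GC content and length were argued against as the whole cause by a median of -0.65 after their removal, against -0.60 before (camera adjusted p = 4.56e-12). A single high NC-miR library stays open, since without replicate 1 the median was -0.31, with adjusted p = 0.00167 at the preset correlation and 0.651 with an estimated correlation, and the mean score of the remaining NC-miR library (1.58) lay below that of miR-29b replicate 2 (1.64). Variation between mice and an action of the injected miR-29 also cannot be told apart, and neither test decided between them. The exact permutation p of the library scores was 0.133, but with 4 and 2 libraries it cannot be below 0.0667. The adjusted p with an estimated correlation was 0.661, and 0 of the 31 lists passed with it in any comparison.

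Genes with a miR-29 seed site lay lower than other genes in miR-29b against NC-miR. For the 7-base or 8-base site, length and GC content could account for it, since 18 of 79 control 7-mers gave a difference as low and the difference from matched genes was -0.02. For the 8-base site alone this stays open, since 2 of 79 control 7-mers but 22 of 79 control 8-mers gave a difference as low. The matched difference of -0.02 leaves repression by miR-29b open, as it cannot be told apart from no effect. With GC content and length fitted across genes, the coefficient of the 7-base or 8-base site was -0.0045 for miR-29b, with 8 of 79 control 7-mers as low. It was -0.0093 for miR-29a, with 0 of 79 as low, and -0.0069 for their mean, with 1 of 79 as low. Between NC-miR day 4 and day 2, where no miR-29 was given, it was 0.014, with 76 of 79 as low. Relative to the mean of all libraries it was -0.0133 and 0.0044 in the miR-29a libraries and -0.0045 and 0.0143 in the NC-miR day 4 libraries, which overlap. For the 8-base site the coefficient was positive, at 0.0064 for miR-29b and 0.0048 for miR-29a, each with 33 of 79 control 7-mers as low. Genes with only the 7-base site were among those it was set against, so it cannot decide on repression. The planned lists of miR-29 targets had medians of 0.06 (outside the matrix) and 0.05 (matrix) with miR-29b, with GC content and length removed.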
